A study of Gallus gallus with 12 samples.

How the data were processed

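RNA of sorted GFP-positive cells from chick neural tubes was measured on 12 Affymetrix chicken arrays, 4 for each of control, NEUROG2 and NEUROG2AQ plasmids, per the labels. Each array held labelled RNA made from 50 ng of total RNA of a pool of 20 embryos. One table of values was deposited. Its log2 signals per probe set had been background-corrected, normalised between arrays and summarised by the authors with RMA, since GCOS, RMA and the affy package are named per the submitters' processing notes, without versions. The labels call the values log signals without a base. Base 2 was inferred from their range, 0.49 to 13.97, because a natural logarithm of that size would exceed what a scanner can record. The values were used as deposited.

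The table held 38535 probe sets. The 37693 whose identifiers mark chicken transcripts were tested, and 842 were left out: 96 Affymetrix controls and 746 others, 57 of them reporter probe sets. Names came from the platform's annotation, brought to current symbols through gene identifiers with a RefSeq gene table of assembly GRCg7b, which was used for names alone. Of the tested probe sets, 27166 had 1 symbol (26851 current, 315 kept under the platform's symbol), 177 had several and 10350 had none here. They covered 13050 genes, 7336 of them with more than 1 probe set. A gene stands for its probe set of highest mean over the 12 arrays.

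All 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with group as the only term, which leaves 9 residual degrees of freedom. The 3 comparisons were NEUROG2 with control, NEUROG2AQ with control and NEUROG2 with NEUROG2AQ. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. For 19 gene lists, camera of limma compared each list with the other genes, with a preset inter-gene correlation of 0.01 and adjustment over all lists and comparisons. camera with a correlation estimated per list was run beside it, and each list's members were also adjusted over the list alone. The 13 group lists were the Notch pathway, proneural factors with partners and ID inhibitors, the early neuronal cascade, postmitotic neuron genes, neuronal subtype factors, progenitor genes, G1 and S phase genes, G2 and M phase genes, DNA replication genes, antiproliferative genes, signalling genes, adhesion genes and stress genes. The 6 marker lists were neural crest, somite, notochord and floor plate, blood and endothelium, surface ectoderm and placode, and endoderm and lateral plate. Not every listed gene had a probe set with its symbol: 25 of 40 stress genes and 27 of 36 early neuronal genes were measured, for example. The stress list covers the least of its members.

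The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Per comparison, the rule names the 10 highest and 10 lowest fold changes among genes past the threshold whose groups do not overlap, with clone names and LOC numbers left out. It adds up to 4 members past the threshold of each list with the largest absolute fold change, or the 2 largest where none passed, and a fixed set: NEUROG2, cyclins D1 to D3, E1, E2, A2, B2 and B3, CDKN1B, CDKN1C, NEUROD1, NEUROD4, DLL1, HES5, HES6, SOX2, SOX3, PAX6, TUBB3 and ELAVL4. Of these, CCNB2 and CDKN1C were not measured.

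The procedure was tested on simulated data made from the arrays' means and spreads with 200 probe sets changed. For NEUROG2 with control it recovered 32.8% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 100% of changes of 2. For NEUROG2AQ with control these shares were 28.4%, 92.5% and 97%, and for NEUROG2 with NEUROG2AQ 26.9%, 85.1% and 95.5%. Unchanged probe sets made up 5.2%, 4% and 4.2% of calls. With no change simulated, limma made 0 calls in each comparison, and a list of 20 genes shifted by 0.5 was called. Probe sets were drawn independently, so correlation between the genes of a list was not simulated. Each share comes from 1 draw. The number of changed probe sets, on which these shares depend, was not varied, so they do not compare power between the real comparisons. The correlation and the shared calls of the NEUROG2 and NEUROG2AQ effects were set beside 100 simulated draws of groups without effects that share controls.

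Alternatives left out the 40% of probe sets with the lowest mean, used eBayes with trend and robust, array weights, only the 2 groups compared, replicate number as a block, median centring, cyclic loess, 1 probe set per gene or the mean of a gene's probe sets, a fold limit of 1 on the log2 scale, or left out each array in turn. Settings chosen after seeing the data left out both control replicate 1 and NEUROG2AQ replicate 4, or added the 3'/5' signal difference as a covariate. The 3'/5' difference is the mean over actin and EF1A control probe sets of the 3' minus the 5' log2 signal, compared between groups by two-sided exact permutation tests. GAPDH was tested the same way after the results were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Array scans and raw intensities were not used, so background correction and summarisation could not be varied.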

Results

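The data were Affymetrix chicken arrays of neural tube cells that had taken up a plasmid by electroporation inside the egg at stages HH10 to HH11. GFP-positive cells were sorted 6 hours later. The 12 arrays fell into 3 groups of 4, each array a biological replicate made from the pooled neural tubes of 20 embryos. The plasmids carried GFP alone (control), GFP with NEUROG2, or GFP with NEUROG2AQ. NEUROG2 is a proneural basic helix-loop-helix transcription factor that drives progenitors of the neural tube towards neuronal fate. The labels give only the name of NEUROG2AQ. In other work that name denotes a form changed in the basic region through which the factor binds DNA. The deposited log2 signals of the tested probe sets had array medians between 2.81 and 2.90, and no pair of arrays held identical values. With 4 arrays a group, the number of arrays limits the precision of each value.

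Group names follow the labels, and the array's NEUROG2 probe set does not check them. Its log2 signal was 5.57 ± 0.36 (mean ± SD, n = 4) in control arrays, 3.90 ± 0.17 in NEUROG2 arrays and 4.64 ± 0.10 in NEUROG2AQ arrays. It was thus lower in the arrays of both expression plasmids, and lowest in the NEUROG2 arrays. The labels state neither the insert's sequence nor which part of the transcript the probes match, so the signal cannot be assigned to plasmid or resident gene from the labels alone.

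The comparison of NEUROG2 with control asks which genes change within hours of adding the factor, and whether cell cycle genes are among them. NEUROG2 cells had more transcripts of neuronal differentiation genes and fewer of progenitor, S phase and mitotic genes. TAGLN3, a cytoskeletal protein of young neurons, rose from 6.31 ± 0.20 to 9.58 ± 0.25 (log2 mean ± SD, n = 4), 9.62-fold. DLL1, a Notch ligand of newborn neurons, rose 3.17-fold, and HES6, an inhibitor of HES1 activity, rose 4.91-fold. PAX6, a progenitor transcription factor, fell by 1.25 ± 0.12 on the log2 scale (SE, n = 4). Among the G1 and S phase cyclins, CCNE2 fell by 0.87 ± 0.10 and CCND1 fell by 0.71 ± 0.14.

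Of 37693 probe sets, 2515 passed an adjusted p of 0.05 in limma, 1242 higher and 1273 lower with NEUROG2. They included the most highly expressed probe set of 1380 of 13050 genes, 679 higher and 701 lower. A change of at least 2-fold was found for 537 of the probe sets, 376 higher and 161 lower. The near balance of directions depended on scaling: 43.7% of calls were higher after median centring and 55.8% after cyclic loess, against 49.4% as deposited. It also depended on single arrays. The share was 43.7% without control replicate 1 (1832 lower) and 55.7% without NEUROG2 replicate 3 (784 lower). Without both control replicate 1 and NEUROG2AQ replicate 4 it was 41.9%. Values given below as log2 fold change ± SE come from limma with 4 arrays a group.

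The 10 largest increases were those of ATP2A3 (3.97 ± 0.21), AQP1 (3.93 ± 0.35), ATOH7 (3.82 ± 0.16), BPIFB2 (3.52 ± 0.17), PENK (3.28 ± 0.24), TAGLN3 (3.27 ± 0.15), NEURL1 (3.12 ± 0.15), RASD2 (3.12 ± 0.12), TNFAIP2 (3.09 ± 0.14) and TMEM140 (3.04 ± 0.14). ATP2A3 pumps calcium into the endoplasmic reticulum, AQP1 is a water channel, and PENK is the precursor of enkephalins. ATOH7, a proneural factor best known from the retina, had a log2 signal of 1.19 ± 0.10 in control arrays and 5.01 ± 0.43 in NEUROG2 arrays (SD, n = 4). The 10 largest decreases were those of CYP26A1 (-2.45 ± 0.19), TNFSF15 (-2.25 ± 0.29), PKDCCA (-2.24 ± 0.13), F3 (-1.89 ± 0.20), CCN2 (-1.86 ± 0.15), BCOR (-1.80 ± 0.19), TSHZ3 (-1.78 ± 0.19), WNT4 (-1.77 ± 0.13), HIST1H111L (-1.68 ± 0.19) and NEUROG2 itself (-1.67 ± 0.15). Control signals of ATOH7 (1.19), AQP1 (2.73), RASD2 (2.79) and TMEM140 (2.81) lay at or below the array medians, close to background, as did TNFSF15 in NEUROG2 arrays (1.68). Their fold changes and ranks are therefore uncertain. CYP26A1 degrades retinoic acid and CCN2 is a secreted matrix protein. These rankings cover genes whose 4 arrays of one group all lay on one side of the other 4. Each gene stands for its probe set of highest mean signal. Of the genes named in this comparison, ATP2A3, NEURL1, TNFAIP2, NHLH1, CXCL12, BTG2, SEMA6D, JAG1, TP53INP1, BCL2L1, ELAVL4, CCNE1, CCNA2, RBL1, DLX5, MCM10, UHRF1, RHOB, FGFR3, E2F8, NEK2, SOX10, TSHZ3, BCOR, TNFSF15 and FLT1 also had a probe set that did not pass, and none had one past the test in the opposite direction.

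**Figure D1:**
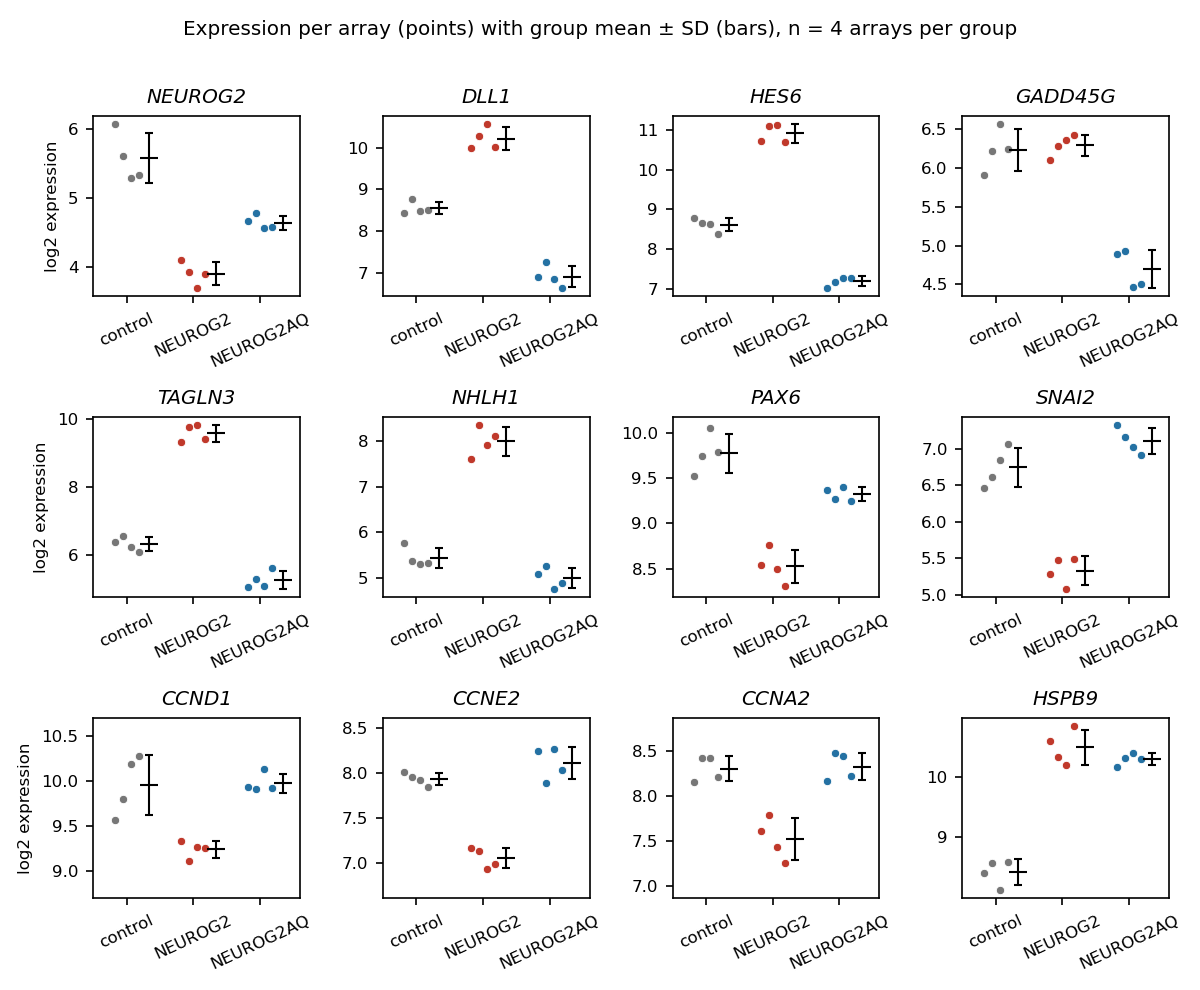
Log2 signal of 12 genes on each array (points: 1 array; bars: group mean ± SD, n = 4), by group; the vertical axes do not start at 0. DLL1, HES6 and TAGLN3 lie above the control arrays with NEUROG2 and below them with NEUROG2AQ, and CCND1, CCNE2 and CCNA2 are lower with NEUROG2 and did not pass the test with NEUROG2AQ.

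Neuronal genes rose as groups. Of 27 measured genes of the early neuronal cascade, 9 rose, 1 fell and 17 did not pass, with 9 higher and 1 lower when adjusted over the list alone. Examples are NHLH1 (2.56 ± 0.16), HES6 (2.30 ± 0.13), PROX1 (1.82 ± 0.13) and DLL1 (1.66 ± 0.15). PROX1 and NEUROD4 read 2.62 and 2.35 in control arrays, close to background, so the sizes of their changes are uncertain, as is that of NRCAM, at 2.32 in NEUROG2 arrays. The member that fell was the chemokine receptor CXCR4 (-1.38 ± 0.13). limma's camera, which compares a list with all other genes, placed this list higher at an adjusted p of 2.66e-07. NEUROD4 rose by 0.49 ± 0.13, and NEUROD1 differed by 0.01 ± 0.10 without passing. Of 36 postmitotic neuron genes, 10 rose, 1 fell and 25 did not pass, with 16 higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.05e-06). The neurofilament genes NEFM (2.82 ± 0.12) and NEFL (2.44 ± 0.18) rose beside TAGLN3, with smaller rises of TUBB3 (0.60 ± 0.15) and ELAVL4 (0.44 ± 0.11). The adhesion molecule NRCAM fell (-1.13 ± 0.30). The calls of NEUROD4, TUBB3, ELAVL4 and NRCAM rest on all arrays being used. Without some of them adjusted p reached 0.107, 0.0916, 0.0824 and 0.0989. All 4 calls ended without control replicate 3, NEUROG2 replicate 3 or NEUROG2 replicate 4. Those of TUBB3 and NEUROD4 also ended without control replicate 2 or 4, that of NRCAM without control replicate 4, those of TUBB3 and NRCAM without NEUROG2 replicate 1, and that of ELAVL4 without control replicate 1 or NEUROG2 replicate 2. Of 22 neuronal subtype factors, VSX1 (1.18 ± 0.16) and LHX1 (0.84 ± 0.13) rose and 20 did not pass. Adjusted over the list alone the count was 2 as well, and the list did not pass (camera adjusted p = 0.552).

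Notch pathway genes and proneural factors moved in both directions, and neither list passed. Of 20 Notch genes, 4 rose, 2 fell and 14 did not pass, with 6 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.208). The ligands DLL1 and JAG1 (1.09 ± 0.16) rose, and the Notch targets HES4 (-1.04 ± 0.11) and NRARP (-0.93 ± 0.14) fell. HES5 differed by -0.14 ± 0.15 without passing. Of 16 proneural factors, partners and ID inhibitors, 5 rose, 3 fell and 8 did not pass, with 5 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.552). ATOH8 rose (0.88 ± 0.14) beside ATOH7. ID1 (1.75 ± 0.13), which binds and blocks partners of proneural factors, rose as well.

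Progenitor genes fell together: of 35 measured, 1 rose, 16 fell and 18 did not pass, with 2 higher and 18 lower when adjusted over the list alone (camera adjusted p = 7.39e-10). ZIC1 (-1.52 ± 0.15), MSX2 (-1.45 ± 0.13), RFX4 (-1.28 ± 0.19) and FGFR3 (-1.27 ± 0.23) fell most. The SoxB1 genes fell less, SOX2 by -0.77 ± 0.18 and SOX3 by -0.48 ± 0.12. The SOX3 call was lost without NEUROG2 replicate 2, 3 or 4, with an adjusted p of up to 0.0759. Signalling genes of the WNT, BMP, FGF, SHH and retinoid pathways also fell as a list. Of 45 measured, 3 rose, 15 fell and 27 did not pass, with 3 higher and 17 lower when adjusted over the list alone (camera adjusted p = 1.07e-06). Among them were CYP26A1, WNT4, the receptor BMPR1B (-1.35 ± 0.22) and the dorsal midline signal WNT3A (-1.27 ± 0.13).

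Cell cycle genes fell in all 3 lists that cover them. Of 24 G1 and S phase cyclins, kinases and E2F genes, 10 fell, none rose and 14 did not pass, with 1 higher and 14 lower when adjusted over the list alone (camera adjusted p = 7.91e-07). MYC (-1.65 ± 0.16), E2F8 (-1.30 ± 0.19) and MYCN (-1.23 ± 0.10) fell most. The cyclin genes CCNE2 (-0.87 ± 0.10, adjusted p = 6.59e-05), CCNA2 (-0.78 ± 0.12, adjusted p = 0.000949), CCND1 (-0.71 ± 0.14, adjusted p = 0.00435) and CCNE1 (-0.62 ± 0.11, adjusted p = 0.00177) fell by limma's test. CCND2 (0.14 ± 0.09, adjusted p = 0.501) and CCND3 (-0.02 ± 0.11, adjusted p = 0.953) did not pass. Of 45 DNA replication genes, 23 fell, none rose and 22 did not pass, with 33 lower when adjusted over the list alone (camera adjusted p = 2.11e-19). They include CDC45 (-1.40 ± 0.13), TK1 (-1.21 ± 0.13), UHRF1 (-1.11 ± 0.14) and MCM10 (-1.09 ± 0.19). Of 35 G2 and M phase genes, 16 fell, none rose and 19 did not pass, with 23 lower when adjusted over the list alone (camera adjusted p = 6.82e-17). NEK2 (-1.34 ± 0.14), FOXM1 (-1.21 ± 0.15), WEE1 (-1.18 ± 0.11) and NUSAP1 (-1.16 ± 0.16) fell most, and CCNB3 (-0.29 ± 0.17) did not pass. CCNB2 and CDKN1C had no probe set with their symbol. These 3 lists, the early neuronal, postmitotic, progenitor and signalling lists also passed camera with an estimated correlation. Adjusted p was then 0.0335 for G1 and S phase, 0.0247 for DNA replication and 0.0384 for G2 and M phase genes. It was 0.0243, 0.00588, 0.00918 and 0.0469 for the early neuronal, postmitotic, progenitor and signalling lists. These values are much larger than those with the preset correlation. That also held for the postmitotic list, whose estimated correlation of -0.017 was below the preset 0.01. A larger correlation alone thus does not account for the rise.

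Genes that restrain proliferation lay near the threshold as a list. Of 20 measured, 5 rose, 1 fell and 14 did not pass, with 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0663). The list passed as higher without the 40% dimmest probe sets (0.0378) and with trend and robust (0.0476). PROX1, BTG2 (1.78 ± 0.11) and GADD45A (1.42 ± 0.13) rose, and the pocket protein gene RBL1 (-0.83 ± 0.15) fell. The kinase inhibitor gene CDKN1B differed by -0.31 ± 0.11 without passing (limma adjusted p = 0.121). Of 25 stress, immediate early and p53 genes, 5 rose, 1 fell and 19 did not pass, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0663). HSPA2 (2.76 ± 0.20), TP53INP1 (0.90 ± 0.10), BCL2L1 (0.69 ± 0.13) and DNAJA1 (0.60 ± 0.13) rose. Without control replicate 2 or NEUROG2 replicate 3 the stress list passed, at 0.0438 and 0.0401. It also passed without the 40% dimmest probe sets (0.0432), with trend and robust (0.0485) and with the mean of a gene's probe sets (0.0417). Of 45 adhesion, cytoskeleton and migration genes, 4 rose, 7 fell and 34 did not pass, with 5 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.237). The chemokine CXCL12 (1.79 ± 0.18) and SEMA6D (1.31 ± 0.23) rose, while its receptor gene CXCR4 and RHOB (-1.16 ± 0.12) fell.

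Markers of other cells were read beside these groups. Of 16 neural crest markers, 5 fell, none rose and 11 did not pass, with 3 higher and 8 lower when adjusted over the list alone. The list passed (camera adjusted p = 0.0011), but not with an estimated correlation (adjusted p = 0.103 with an estimated correlation). SOX10 (-1.50 ± 0.16), SNAI2 (-1.41 ± 0.14), MSX1 (-1.12 ± 0.13) and LMO4 (-0.88 ± 0.12) fell. Of 10 notochord and floor plate markers, NOG (-0.58 ± 0.15) fell and 9 did not pass, with 2 lower when adjusted over the list alone. This list passed (camera adjusted p = 0.0123), but not with an estimated correlation (adjusted p = 0.334 with an estimated correlation) and not without control replicate 1 (adjusted p = 0.234). NOG itself was lost without control replicate 2 or NEUROG2 replicate 2, 3 or 4, with an adjusted p of up to 0.0919. The remaining marker lists did not pass. None of 19 somite markers passed, also when adjusted over the list alone (camera adjusted p = 0.532), with TWIST1 at -0.41 ± 0.46 and FOXC2 at -0.41 ± 0.25. Without control replicate 1 these were 0.07 and -0.18. Of 25 blood and endothelial markers FLT1 fell (-0.50 ± 0.13) and 24 did not pass, with 0 when adjusted over the list alone (camera adjusted p = 0.248). The FLT1 call was lost without control replicate 3 or 4 or NEUROG2 replicate 1, 3 or 4, with an adjusted p of up to 0.11. FLT1 read 1.65 in control replicate 1 and 1.77 on average in the other controls, below the array medians. That is close to background, so the size of its change is uncertain. Of 19 surface ectoderm and placode markers DLX5 fell (-0.95 ± 0.10) and 18 did not pass, with 1 lower when adjusted over the list alone (camera adjusted p = 0.552). None of 21 endoderm and lateral plate markers passed, also when adjusted over the list alone (camera adjusted p = 0.792), with GATA5 at 0.32 ± 0.15 and its other probe set past the test at 0.64. FOXA2, in this list and the notochord list, differed by -0.84 ± 0.25 without passing (limma adjusted p = 0.0605). It passed without control replicate 4 (0.0136) or NEUROG2 replicate 1 (0.0365), without the 40% dimmest probe sets (0.0498) and with the 3'/5' covariate (0.0333), and reached 0.191 without NEUROG2 replicate 3.

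Control replicate 1 stood apart in these markers. It had the highest value of the 4 controls for 15 of 19 somite, 6 of 10 notochord and floor plate and 14 of 21 endoderm and lateral plate markers. The mean log2 signal over the somite markers was 3.90 in control replicate 1 and 3.09 to 3.37 in the other controls, and over the notochord and floor plate markers 5.32 against 4.55 to 4.81. Over the endoderm and lateral plate markers it was 2.95 against 2.65 to 2.75. The blood and endothelial markers were highest in control replicate 4, at 4.02 against 3.26 to 3.59, with HBZ at 8.97. Control replicate 1 and NEUROG2AQ replicate 4 also lay apart from their groups on the second principal component, at 52.3 and 30.2. The 3'/5' log2 signal difference of actin and EF1A control probes, which grows as RNA is degraded, was 1.80 ± 0.12 in control, 1.74 ± 0.15 in NEUROG2 and 1.95 ± 0.29 in NEUROG2AQ arrays (SD, n = 4). Two-sided exact permutation tests gave p = 0.514, 0.4 and 0.229 for NEUROG2 against control, NEUROG2AQ against control and NEUROG2 against NEUROG2AQ, each 0.514 after adjustment over the 3. For GAPDH, looked at later, the difference was 0.35 ± 0.08, 0.21 ± 0.08 and 0.28 ± 0.11 in control, NEUROG2 and NEUROG2AQ arrays (SD, n = 4). Exact permutation tests gave p = 0.0857, 0.343 and 0.371 for the same comparisons, and 0.257, 0.371 and 0.371 after adjustment. The smallest p such a test allows with 4 against 4 arrays is 0.0286. For actin and EF1A, NEUROG2AQ replicate 4 read 1.52 and the other NEUROG2AQ arrays 2.03 to 2.14. These others lay above every control array (1.72 to 1.99) and every NEUROG2 array (1.59 to 1.90). The tests, which include replicate 4, therefore do not exclude a link between the 3'/5' difference and the groups. Without both control replicate 1 and NEUROG2AQ replicate 4, a setting chosen after seeing the data, 3682 probe sets passed for NEUROG2 against control.

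**Figure D2:**
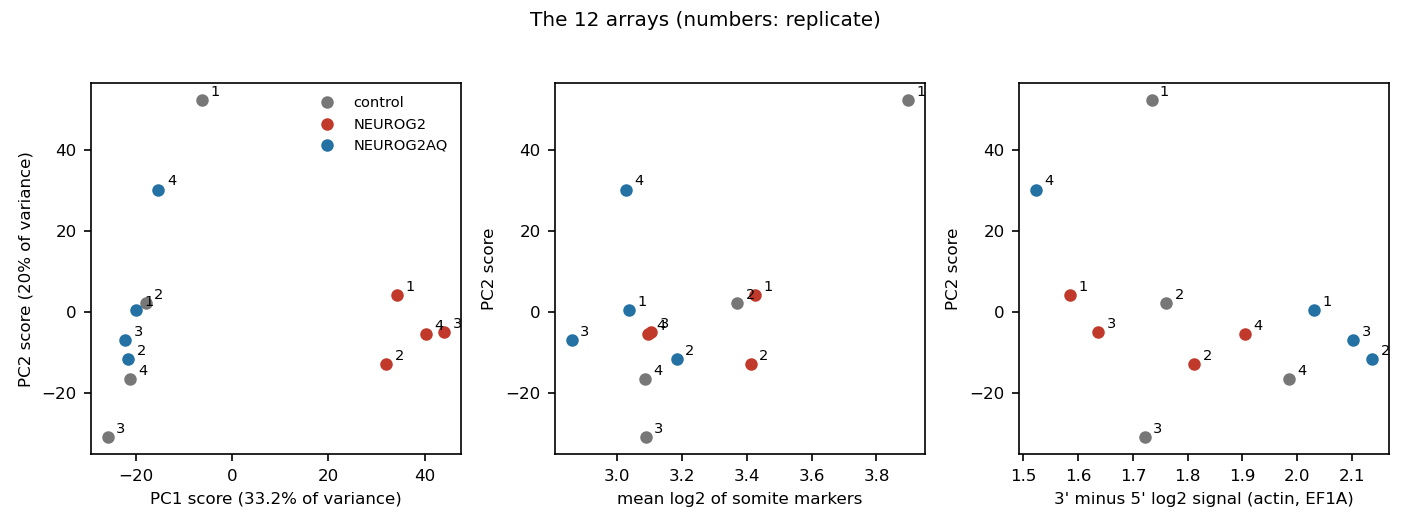
Each point is 1 of the 12 arrays, coloured by group and numbered by replicate: its score on the second principal component of the tested log2 signals (vertical axes; 20% of the variance) against its score on the first (33.2%), its mean log2 signal over the somite markers, and its 3' minus 5' log2 signal of actin and EF1A. Control replicate 1 has the highest somite marker mean and NEUROG2AQ replicate 4 the lowest 3'/5' difference of the 12. The other NEUROG2AQ arrays have higher 3'/5' differences than every control and NEUROG2 array.

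The comparison of NEUROG2AQ with control asks what the changed form does to the same cells. Few genes passed, and most that did were lower with NEUROG2AQ. DLL1 fell from 8.55 ± 0.15 to 6.91 ± 0.26 (log2 mean ± SD, n = 4), 3.12-fold. HES6 fell by 1.42 ± 0.13 and GADD45G, a stress-inducible growth arrest gene, fell by 1.53 ± 0.15 on the log2 scale (SE, n = 4). The small heat shock protein gene HSPB9 (1.86 ± 0.14) and HSPA2 (1.66 ± 0.20), another heat shock gene, rose. The cyclin genes CCND1 (0.02 ± 0.14), CCNE2 (0.18 ± 0.10) and CCNA2 (0.02 ± 0.12) did not pass. CCNE1 and CDKN1B did not pass either, although their values in the other comparisons place both below control. Of 24 G1 and S phase genes, 3 were lower and 1 higher when adjusted over the list alone.

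In limma 25 of 37693 probe sets passed, 3 higher and 22 lower, and 2596 had an unadjusted p under 0.05. They included the most highly expressed probe set of 14 genes, 2 higher and 12 lower. The other 9 genes lower were GFRA1 (-1.13 ± 0.19), JAG1 (-1.10 ± 0.16), TAGLN3 (-1.06 ± 0.15), NEUROG2 (-0.93 ± 0.15), SULF1 (-0.88 ± 0.14), NIN (-0.78 ± 0.13), AMOTL2 (-0.75 ± 0.11), NOTCH1 (-0.66 ± 0.09) and SFRP2 (-0.64 ± 0.10). For NIN, AMOTL2, SULF1, NOTCH1 and JAG1 none of the gene's other probe sets passed. DLL1 (adjusted p = 0.000123), HES6 (0.000113), GADD45G (0.000174), HSPB9 (4.6e-05) and HSPA2 (0.00346) passed in every alternative in which they were tested, while each of these 9 was lost in some. Leaving out 1 array ended the call of SFRP2 for control replicate 2 and NEUROG2AQ replicates 3 and 4 (adjusted p up to 0.103), and that of NOTCH1 for NEUROG2AQ replicates 1, 3 and 4 (up to 0.056). TAGLN3 was lost without control replicate 2 or NEUROG2AQ replicate 1, 2 or 3 (up to 0.0783), and JAG1 without control replicate 2 or NEUROG2AQ replicate 1, 3 or 4 (up to 0.0821). AMOTL2 was lost without control replicate 2 or 4 or NEUROG2AQ replicate 1, 2 or 3 (up to 0.103). SULF1 was lost without control replicate 4, NEUROG2 replicate 1 or 4 or any NEUROG2AQ array (up to 0.113). NEUROG2 was lost without control replicate 2, NEUROG2 replicate 1, 2 or 4 or any NEUROG2AQ array (up to 0.138). GFRA1 kept its call only without control replicate 2 or NEUROG2AQ replicate 2, and NIN only without control replicate 1 or NEUROG2AQ replicate 3 (otherwise up to 0.124 and 0.144). The number of calls moved by over 1.5 times with single arrays: 11 without control replicate 2, 13 without NEUROG2AQ replicate 1, 14 without NEUROG2AQ replicate 2, 10 without NEUROG2AQ replicate 3 and 11 without NEUROG2AQ replicate 4. When the fit held these 2 groups alone, 8 probe sets passed.

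**Figure D3:**
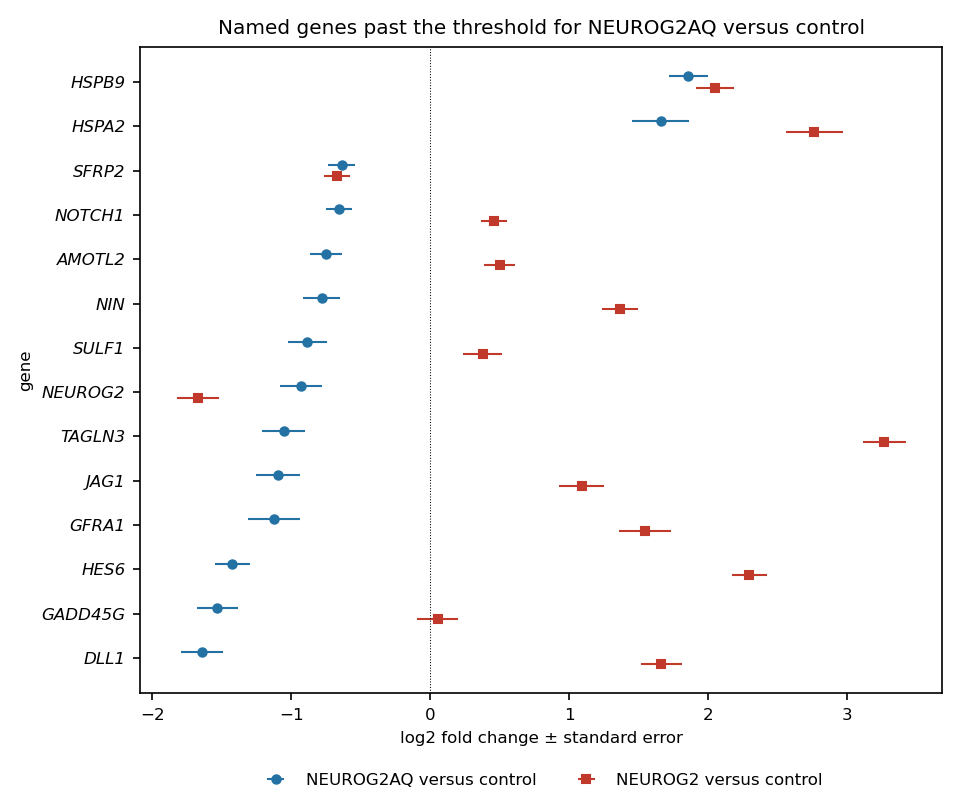
Log2 fold change ± SE against control (horizontal axis) of the 14 genes past the test for NEUROG2AQ, with NEUROG2AQ (circles) and with NEUROG2 (squares), n = 4 arrays a group. DLL1, HES6, JAG1 and TAGLN3 lie below 0 with NEUROG2AQ and above 0 with NEUROG2, while HSPB9 and HSPA2 lie above 0 with both and SFRP2 and NEUROG2 below 0 with both.

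The early neuronal and proneural lists were lower with NEUROG2AQ. Of 27 early neuronal genes 3 fell (DLL1, GADD45G and HES6) and 24 did not pass, with 6 lower when adjusted over the list alone (camera adjusted p = 3.78e-08). Of 20 Notch genes 3 fell (DLL1, JAG1 and NOTCH1) and 17 did not pass, with 4 lower when adjusted over the list alone (camera adjusted p = 1.49e-06). Of 16 proneural factors, partners and ID inhibitors NEUROG2 fell and 15 did not pass, with 8 lower when adjusted over the list alone. All 16 had a negative fold change, with a median of -0.41 (camera adjusted p = 2.44e-11). Of 35 progenitor genes NOTCH1 fell and 34 did not pass, with 8 lower when adjusted over the list alone (camera adjusted p = 7.16e-12). SOX2 (-0.79 ± 0.18, limma adjusted p = 0.176) and PAX6 (-0.46 ± 0.12, limma adjusted p = 0.335) did not pass. Both were lower in all 4 NEUROG2AQ arrays than in every control array. That adds little, since 4% of all probe sets did not overlap between these groups in either direction, and chance gives 2.86%. Of 20 antiproliferative genes GADD45G fell and 19 did not pass, with 4 lower when adjusted over the list alone (camera adjusted p = 0.00135). Of 45 signalling genes SFRP2, a secreted WNT antagonist, fell and 44 did not pass, with 4 lower when adjusted over the list alone (camera adjusted p = 1.61e-08). Of 25 stress genes HSPA2 rose and 24 did not pass, with 8 higher and 1 lower when adjusted over the list alone, and the list was higher (camera adjusted p = 0.00119). Some of these lists share members, so they are not independent of each other. DLL1 is in the early neuronal and Notch lists, and GADD45G in the early neuronal and antiproliferative lists. NOTCH1 is in the Notch and progenitor lists. Each list of this paragraph also passed camera with an estimated correlation. Adjusted p was then 0.0243 for early neuronal, 0.0171 for Notch, 0.0156 for proneural and 0.00588 for progenitor genes. It was 0.0243, 0.0278 and 0.0247 for the antiproliferative, signalling and stress lists.

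A further 6 lists passed with the preset correlation and not with an estimated one. Of 35 G2 and M phase genes none passed alone or when adjusted over the list alone, and the list was higher (median 0.14, camera adjusted p = 0.00141, adjusted p = 0.401 with an estimated correlation). Of 45 DNA replication genes none passed alone or when adjusted over the list alone, and the list was higher (median 0.08, camera adjusted p = 0.00784, adjusted p = 0.476 with an estimated correlation). Of 45 adhesion genes none passed and 3 were lower when adjusted over the list alone (camera adjusted p = 9.07e-05, adjusted p = 0.0722 with an estimated correlation). Values of single members were 1.28 ± 0.38 for PRIM2, 0.82 ± 0.46 for SMC2 and -0.82 ± 0.18 for CXCL12. SMC2 ranged from 0.14 without control replicate 1 to 1.13 without control replicate 3. PRIM2 passed without both control replicate 1 and NEUROG2AQ replicate 4 (0.0165), and CXCL12 with the 3'/5' covariate (0.0413). Somite (camera adjusted p = 0.00125), notochord (0.00224) and blood and endothelial (0.00784) markers were lower as lists. None of their members passed, and 2, 1 and 0 were lower when adjusted over the list alone. Adjusted p was 0.342, 0.224 and 0.168 with an estimated correlation. Without control replicate 1, the array with the highest somite and notochord marker means, adjusted p was 0.246, 0.326 and 0.107 for these marker lists and 0.0799 for the G2 and M phase list. Without control replicate 4 it was 0.0647 for the DNA replication list, and with the mean of a gene's probe sets 0.0677 for the blood list. Without both control replicate 1 and NEUROG2AQ replicate 4 it was 0.212, 0.232 and 0.232 for the somite, notochord and blood lists and 0.0558 for DNA replication. Member values were -1.21 ± 0.46 for TWIST1, -0.78 ± 0.34 for NOTO and -1.73 ± 0.59 for HBZ. TWIST1 and NOTO shrank to -0.73 and -0.36 without control replicate 1, and HBZ to -1.02 without control replicate 4.

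The other 6 lists did not pass. Of 36 postmitotic genes TAGLN3 fell and 35 did not pass, with 1 lower when adjusted over the list alone (camera adjusted p = 0.248). Of 24 G1 and S phase genes none passed, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.792). Its median was 0.03 while camera's direction was lower, and CDK6 was at -0.43 ± 0.13 and CKS2 at 0.57 ± 0.16. Neuronal subtype factors, neural crest, surface ectoderm and endoderm markers had no member past the test, also when adjusted over the list alone (camera adjusted p = 0.936, 0.724, 0.936 and 0.792). The median and camera's direction also differed in sign for the subtype factors, the endoderm markers and the surface ectoderm markers.

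**Figure D4:**
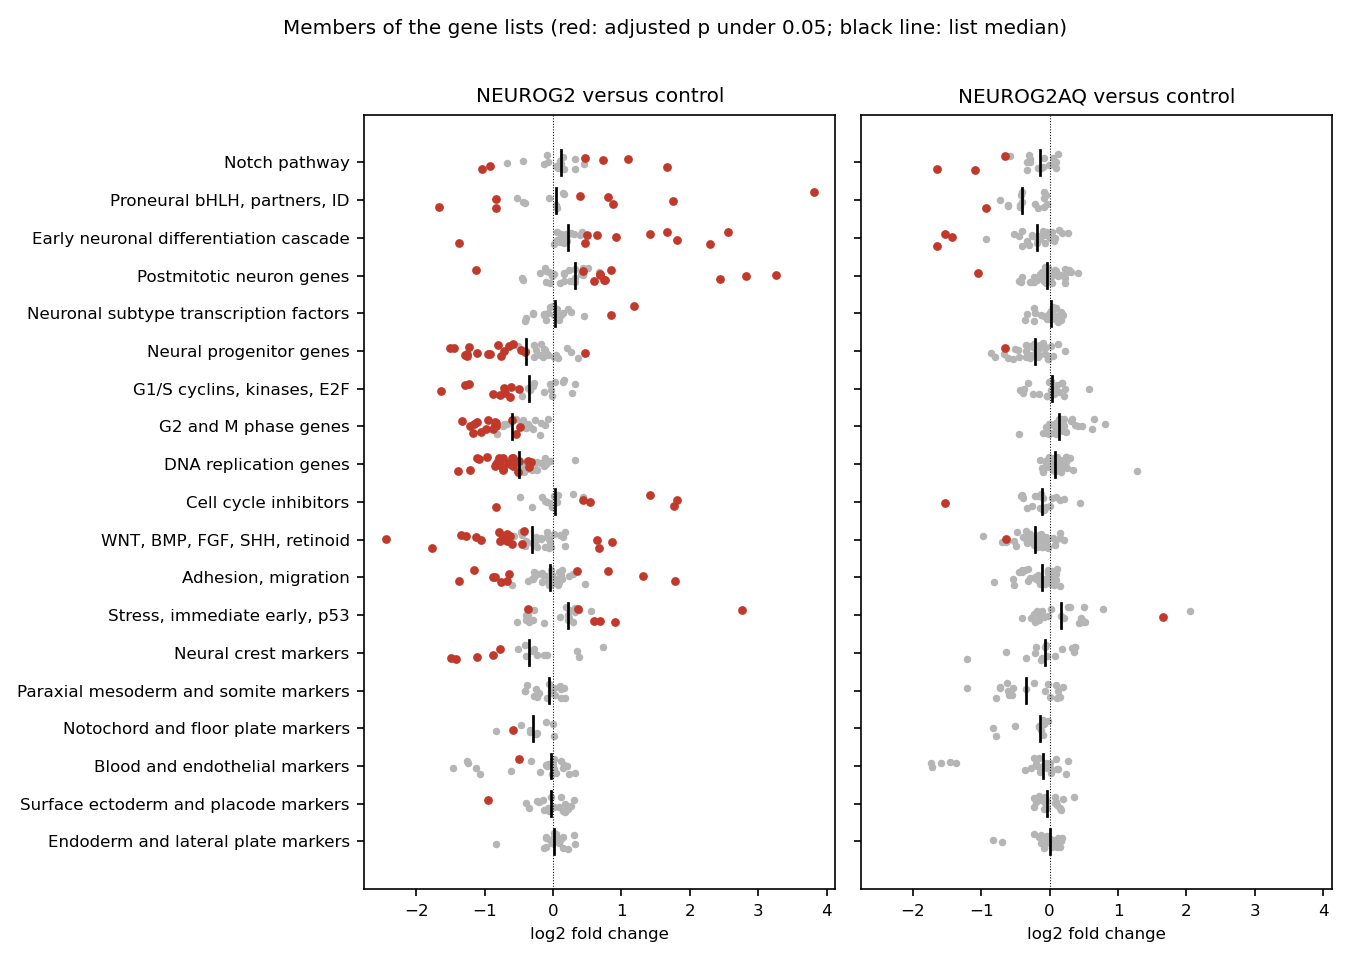
Log2 fold change (horizontal axis) of each measured member of the 19 gene lists for NEUROG2 (left) and NEUROG2AQ (right) against control, with members past an adjusted p of 0.05 in red and the list median as a black line. With NEUROG2 the medians of the 3 cell cycle lists are -0.35, -0.60 and -0.50; with NEUROG2AQ none of their members passed.

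The direct comparison of NEUROG2 with NEUROG2AQ asks which changes differ between the forms. Neuronal genes were higher and cell cycle genes lower with NEUROG2 than with NEUROG2AQ. HES6 was 13.2-fold higher (10.92 ± 0.24 against 7.20 ± 0.12, log2 mean ± SD, n = 4) and DLL1 9.88-fold higher (10.21 ± 0.28 against 6.91 ± 0.26). The neurofilament gene NEFM was higher by 3.25 ± 0.12 on the log2 scale (SE, n = 4). CCNE2 (-1.05 ± 0.10), CCNA2 (-0.80 ± 0.12) and CCND1 (-0.73 ± 0.14) were lower. CCND2 was higher (0.38 ± 0.09), and CCNE1 (-0.22 ± 0.11) did not pass, although 1 of its other probe sets did (-0.50).

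In limma 2286 probe sets passed, 1385 higher and 901 lower with NEUROG2, and 574 of them differed at least 2-fold, 437 higher and 137 lower. They included the most highly expressed probe set of 1260 genes, 722 higher and 538 lower. The largest increases were those of ATP2A3 (4.59 ± 0.21), TAGLN3 (4.32 ± 0.15), BPIFB2 (4.26 ± 0.17), POSTN (4.16 ± 0.30), AQP1 (4.04 ± 0.35), ATOH7 (3.87 ± 0.16), HES6 (3.72 ± 0.13), CHN2 (3.60 ± 0.16), TNFAIP2 (3.54 ± 0.14) and TMEM140 (3.53 ± 0.14). The largest decreases were those of CYP26A1 (-2.27 ± 0.19), PKDCCA (-1.83 ± 0.13), SNAI2 (-1.78 ± 0.14), WNT4 (-1.73 ± 0.13), SGO1 (-1.70 ± 0.22), TNFSF15 (-1.64 ± 0.29), GSG2 (-1.63 ± 0.15), NEDD9 (-1.53 ± 0.17), F3 (-1.52 ± 0.20) and HIST1H111L (-1.52 ± 0.19). The ranks of ATOH7, CHN2, TMEM140 and AQP1 are again uncertain, with signals of 1.13, 2.17, 2.32 and 2.62 in NEUROG2AQ arrays, and so are those of TNFSF15 and NEDD9, at 1.68 and 2.14 in NEUROG2 arrays. ATP2A3, CHN2, TNFAIP2, NEDD9 and TNFSF15 also had a probe set that did not pass, as had JAG1, NOTCH1, CCNA2, CCND2, BTG2, E2F8, NEK2 and SOX10, named below. SGO1 protects cohesion of sister chromatids and GSG2 is the mitotic histone kinase haspin. The share of calls that were higher was 60.6%, against 50.6% without both control replicate 1 and NEUROG2AQ replicate 4, where 2957 probe sets passed. With 1 array left out it ranged from 54.6% (control replicate 1) to 66.6% (NEUROG2 replicate 3, with 583 lower).

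Of 35 G2 and M phase genes 23 were lower, none higher and 12 did not pass, with 33 lower when adjusted over the list alone (camera adjusted p = 1.48e-22). NEK2 (-1.42 ± 0.14), NUSAP1 (-1.30 ± 0.16), AURKB (-1.20 ± 0.12) and KIF23 (-1.20 ± 0.14) differed most. Of 45 DNA replication genes 26 were lower, none higher and 19 did not pass, with 37 lower when adjusted over the list alone (camera adjusted p = 5.86e-24), CDC45 (-1.47 ± 0.13) and TK1 (-1.34 ± 0.13) among them. Of 24 G1 and S phase genes 1 was higher, 11 lower and 12 did not pass, with 2 higher and 12 lower when adjusted over the list alone (camera adjusted p = 2.38e-06). E2F8 (-1.44 ± 0.18), MYC (-1.27 ± 0.16) and CKS2 (-1.03 ± 0.16) were lower. The CCND2 call was lost without NEUROG2 replicate 2 or NEUROG2AQ replicate 1 or 3, with an adjusted p of up to 0.0562. CCNB3 (-0.62 ± 0.17) passed with all arrays (adjusted p = 0.0461) and was lost in 9 of the 12 fits that left out 1 array, up to 0.157. It passed without control replicate 1, control replicate 3 or NEUROG2 replicate 2. Of 20 antiproliferative genes 7 were higher, 1 lower and 12 did not pass, with 7 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00187). BTG2 (2.20 ± 0.11), PROX1 (2.07 ± 0.13, from 2.36 and thus near background) and GADD45G (1.58 ± 0.15) were higher, and CDKN1B (0.08 ± 0.11) did not pass. These 4 lists also passed camera with an estimated correlation, as did the early neuronal and postmitotic lists. Adjusted p was then 0.0243 for G2 and M phase, 0.0235 for DNA replication and 0.0384 for G1 and S phase genes. It was 0.0243, 0.0114 and 0.00588 for the antiproliferative, early neuronal and postmitotic lists.

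Of 27 early neuronal genes 11 were higher, 1 lower and 15 did not pass, with 16 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.16e-12). Of 36 postmitotic genes 12 were higher, 1 lower and 23 did not pass, with 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 6.02e-07). NEFL (2.54 ± 0.18) and ELAVL4 (0.73 ± 0.11) were higher, and TUBB3 (0.32 ± 0.15) did not pass. The Notch list was higher, with 5 genes higher, 2 lower and 13 not past, and 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00224, adjusted p = 0.061 with an estimated correlation). JAG1 (2.19 ± 0.16) and NOTCH1 (1.12 ± 0.09) were higher beside DLL1. Proneural factors, partners and ID inhibitors had 5 genes higher, 2 lower and 9 not past, with 5 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000759, adjusted p = 0.103 with an estimated correlation). The inhibitors ID1 (2.19 ± 0.13) and ID4 (1.41 ± 0.12) were among those higher. Of 35 progenitor genes 3 were higher, 9 lower and 23 did not pass, with 6 higher and 14 lower when adjusted over the list alone (camera adjusted p = 0.00305, adjusted p = 0.0832 with an estimated correlation). MSX2 (-1.30 ± 0.13) and PAX6 (-0.80 ± 0.12) were lower, and SOX2 (0.02 ± 0.18) and SOX3 (-0.17 ± 0.12) did not pass. Of 16 neural crest markers 3 were higher, 6 lower and 7 did not pass, with 3 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.00442, adjusted p = 0.154 with an estimated correlation). SNAI2 and SOX10 (-1.43 ± 0.16) were lower and SNAI1 (1.37 ± 0.21) was higher. The other 9 lists did not pass. The signalling list was nearest (camera adjusted p = 0.065) and passed without NEUROG2 replicate 1, NEUROG2 replicate 2 or NEUROG2AQ replicate 3, at 0.0335, 0.0462 and 0.0422.

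Across all 37693 probe sets the effects of the plasmids against control had a Pearson r of 0.234. Genes are not independent replicates, and both effects share the control arrays, which alone gave a mean r of 0.5 in simulated groups without any effect. With each comparison given its own 2 controls, r lay between -0.179 and 0.0799 over 6 ways of dividing them. The covariance was 0.0119, and 0.0116 in the simulated groups, which used 1 spread per probe set for all groups. With each comparison given its own 2 controls it was -0.00313 on average. The near match with the simulated groups therefore does not show that the effects are unrelated. Without control replicate 1, r was 0.356. Of the probe sets called in both comparisons, 12 were higher with NEUROG2 and lower with NEUROG2AQ, where independent lists would share 0.725. A further 3 were higher with both (0.0989 for independent lists), 2 lower with both (0.743) and 0 lower with NEUROG2 and higher with NEUROG2AQ (0.101). Independent lists leave out the shared controls, which raise overlap in the same direction. Simulated groups without effects that share controls gave 0 in every direction. Without effects limma made 0 calls in each comparison, so shared calls could hardly occur. This 0 therefore gives no expectation for shared calls under shared controls. With each comparison given its own 2 controls, 4 to 17 were higher with NEUROG2 and lower with NEUROG2AQ, 2 to 3 higher with both and 0 to 6 lower with both.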

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

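The tests of the arrays that stand apart, in the closing paragraph of this part, were chosen after the result was seen. In 402 groups of 4 arrays, the highest or lowest array was compared with its group by its gap to the nearest array over the group's range. This ratio passed Dixon's critical value in 20 groups, and chance gives about 1 in 20. The ratio stands in parentheses after the log2 signals.

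Control replicate 1 lay apart in 5 genes: NHLH1 read 5.76 against a mean of 5.33 in the other 3 arrays (0.868), NEUROD4 2.67 against 2.24 (0.875), PKDCCA 6.09 against 6.45 (0.837), FOXP1 5.22 against 5.99 (0.894) and ATF3 2.40 against 2.82 (0.972). In control replicate 3, CRABP1 read 7.59 against 8.05 (0.935) and NEDD9 3.45 against 3.75 (0.881). In control replicate 4, TTR read 5.74 against 3.32 (0.948) and the 3'/5' signal difference of actin and EF1A was 1.99 against 1.74 (0.853). Among NEUROG2 arrays, BTG2 read 9.51 against 9.73 in replicate 1 (0.872), MSX1 8.32 against 8.67 (0.971) and AURKB 7.96 against 7.54 (0.864) in replicate 2, and CYP26A1 5.16 against 5.84 in replicate 3 (0.987). Among NEUROG2AQ arrays, ATOH7 read 1.27 against 1.09 (0.877) and CCND2 7.93 against 7.75 (0.835) in replicate 2, and PENK 6.53 against 5.89 (0.955) and CCND1 10.13 against 9.92 (0.925) in replicate 3. In NEUROG2AQ replicate 4, WNT3A read 7.67 against 7.84 (0.852), F3 4.44 against 4.74 (0.871) and SGO1 6.28 against 6.62 (0.845).

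Control replicate 1 and NEUROG2AQ replicate 4 lay apart from their groups on the second principal component. For control replicate 1, the 29 somite and notochord markers deviated from the other controls by 0.703 on average, above the 0.256 of the highest array other than NEUROG2AQ replicate 4 (MEOX1 6.41 against 4.81, TBXT 7.40 against 6.28, CHRD 6.74 against 4.86, COL2A1 8.75 against 8.31), and its 3'/5' difference of 1.734 lay inside the range of the other controls. For NEUROG2AQ replicate 4 the markers deviated by 0.007, which argues against such cells, while its 3'/5' difference of 1.523 lay below the 2.03 to 2.14 of the other NEUROG2AQ arrays. Its GAPDH difference of 0.228 lay inside their range of 0.173 to 0.419. NEUROG2 replicates 1 and 3 had differences of 1.586 and 1.637 for actin and EF1A. Their scores on the component were 4.1 and -5, against 30.2, so a low difference alone does not place an array there. Candidate explanations are RNA of different integrity in NEUROG2AQ replicate 4 and more cells of other tissues in the pool of control replicate 1, which sorting by GFP would keep only if they carried the plasmid; which tissue is open, since this array was also highest of the controls for 14 of 21 endoderm and lateral plate markers, and 3 of the 19 somite, 2 of the 10 notochord and 4 of the 21 endoderm markers are in another list, with 12, 9 and 6 above the median probe set in the other controls. Posterior HOX genes of paralogue groups 9 to 13 deviated by 0.128 and 0.261, below the highest other array (0.304) and not below 0, so a difference in axial level of the pools cannot be told apart from the rest.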

How the results depend on the processing

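The settings without both control replicate 1 and NEUROG2AQ replicate 4 and with the 3'/5' covariate were chosen after seeing the data. No named gene reversed its direction past the threshold in any setting, and 72 of 79, 5 of 14 and 70 of 77 named calls (NEUROG2 with control, NEUROG2AQ with control, NEUROG2 with NEUROG2AQ) passed in every setting in which they were tested. With a limit of 2-fold the counts were 537, 14 and 574, fewer by construction, and with 1 probe set per gene 1580 and 1441 for NEUROG2 with control and with NEUROG2AQ, since fewer are tested. NEUROG2AQ with control gave 44 probe sets with trend and robust and 8 with only the 2 groups compared. Fewer arrays stand behind the spread in the latter setting. Yet it gave 2694 against 2286 for NEUROG2 with NEUROG2AQ, and 2097 against 2515 for NEUROG2 with control. The causes of these changes were not tested. With an estimated correlation 7 lists passed for NEUROG2AQ with control and 6 for NEUROG2 with NEUROG2AQ, against 13 and 10. Leaving out each array gave 1771 to 3253 probe sets and 8 to 10 lists for NEUROG2 with control, 10 to 30 and 9 to 13 for NEUROG2AQ with control, and 1744 to 2940 and 10 to 11 for NEUROG2 with NEUROG2AQ. The count for NEUROG2AQ with control fell to 11 without control replicate 2, 13 without NEUROG2AQ replicate 1, 14 without NEUROG2AQ replicate 2, 10 without NEUROG2AQ replicate 3 and 11 without NEUROG2AQ replicate 4. The correlation of effects ranged from 0.196 to 0.356, the highest without control replicate 1. Without both arrays that stand apart the counts were 3682, 21 and 2957, and with the 3'/5' covariate 2618, 31 and 2090. Whether replicate numbers mark shared days is open. Of 12 same-number pairs 5 had a residual correlation above 0.1, from -0.3 to 0.228, and 5 arrays matched their own number best, 3 of them among the 4 pairs of NEUROG2 with control (0.178, 0.228 and 0.131, with -0.019 for replicate 3). With replicate number as a block the counts were 2463, 28 and 2249. Under the block FOXA2 passed for NEUROG2 with control (0.0405) and NOG for NEUROG2 with NEUROG2AQ (0.0372). NRCAM did not pass for NEUROG2 with control (0.0566), SULF1 and GFRA1 for NEUROG2AQ with control (0.0896 and 0.0953), and SOX18, NEUROD4 and NRCAM for NEUROG2 with NEUROG2AQ (0.0604, 0.0708 and 0.0788). The median fold change of all probe sets moved by less than 0.1 on the log2 scale under median centring and cyclic loess. Genes with signals near the array median, about 2.8 on the log2 scale, lie close to background, where the size of a change in either direction is uncertain.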

Other observations

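All tests in this part except those of other splits of the arrays were chosen after the result was seen, and so were the 4 gene families of these first 2 paragraphs. HOX genes, which set position along the body axis, were lower with NEUROG2 in its comparison with control: of 29 measured, 10 fell, none rose and 19 did not pass, with 12 lower when adjusted over the list alone. HOXA4 (-1.51 ± 0.15, SE, n = 4), HOXA6 (-1.33 ± 0.17), HOXA3 (-0.99 ± 0.13) and HOXD4 (-0.96 ± 0.12) fell most among those past the threshold, while HOXA9 (-1.79 ± 0.55) and HOXC9 (-1.01 ± 0.65) did not pass. The count was 10 after median centring, 8 after cyclic loess and 7 without both control replicate 1 and NEUROG2AQ replicate 4. HOXC8, which passed, read 2.61 in control arrays, close to background. So did some members that did not pass, such as HOXD10 (1.65) and HOXD12 (1.76), where a fall could hardly be seen. Others that did not pass, such as HOXB1 (8.84) and HOXB8 (6.51), read well above background. The family passed limma's camera (adjusted p = 0.000306 over 4 families and 3 comparisons), but not with an estimated correlation (adjusted p = 0.303 with an estimated correlation). With NEUROG2AQ none of the 29 passed against control, with a median of -0.16 (camera adjusted p = 0.00231, adjusted p = 0.303 with an estimated correlation), and 6 were lower with NEUROG2 than with NEUROG2AQ (camera adjusted p = 0.0114, adjusted p = 0.303 with an estimated correlation).

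Of 62 heat shock and DNAJ co-chaperone genes, 8 of them in the fixed lists, 6 rose and 2 fell with NEUROG2, with 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.366). The family's median was -0.01 while camera's direction was higher, and the median was 0.03 after cyclic loess. Without both control replicate 1 and NEUROG2AQ replicate 4, 7 were higher and 5 lower. HSPB9 rose by 2.05 ± 0.14 with NEUROG2 and by 1.86 ± 0.14 with NEUROG2AQ, and HSPA2 by 2.76 ± 0.20 and 1.66 ± 0.20. The difference between the forms was 0.19 for HSPB9 (limma adjusted p = 0.583) and 1.11 for HSPA2 (limma adjusted p = 0.00287). With NEUROG2AQ these were the 2 members past the test, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00151, adjusted p = 0.303 with an estimated correlation). Of the others that rose with NEUROG2, HSPA8, DNAJA1 and DNAJA4 did not differ between the forms past the test (limma adjusted p = 0.595, 0.849 and 0.637). HSPA12A did (limma adjusted p = 0.0109). The counts of calls thus do not compare the sizes of the changes. Of 31 kinesin genes, 5 of them in the fixed lists, 7 fell with NEUROG2 and none rose, with 2 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.00809, adjusted p = 0.303 with an estimated correlation). KIF23 (-1.11 ± 0.14), KIF18B (-0.97 ± 0.13) and KIF2C (-0.88 ± 0.18), motors of mitosis, fell. The count was 5 after cyclic loess and 12 without both control replicate 1 and NEUROG2AQ replicate 4. Of 56 ribosomal protein genes none passed in limma with NEUROG2 (camera adjusted p = 0.116).

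The array's NEUROG2 probe set was lower in NEUROG2 and NEUROG2AQ arrays than in controls. An exchange of control and NEUROG2 labels is argued against by the early neuronal list, whose median fold change with NEUROG2 stayed above 0 without each array in turn, at 0.193 or more. Whether the probe set reads the plasmid's transcript or the resident gene is open, since the insert and the probes' place in the transcript are not given. A candidate explanation is lower expression of the resident gene, which was not tested. A reporter probe set outside the tested ones was also lower with NEUROG2 and NEUROG2AQ, at 7.24, 5.31 and 4.79 in control, NEUROG2 and NEUROG2AQ arrays, and none of the 57 was higher past the threshold.

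The 376 probe sets at least 2-fold higher with NEUROG2 leaned lower with NEUROG2AQ, with a median of -0.10 against control and 64.1% below 0, against 48.7% of all. Sharing controls moves both comparisons the same way, so it would raise this median. Without each array in turn it was -0.074 or lower, and with the 3'/5' covariate -0.121. As a hypothesis, NEUROG2AQ may lower genes that NEUROG2 raises. The 161 probe sets at least 2-fold lower with NEUROG2 leaned lower with NEUROG2AQ too, with a median of -0.24 and 72% below 0. Here shared controls remain possible as a cause. With probe sets chosen by 2 controls and read against the other 2, the median lay between -0.209 and 0.104 over the 6 divisions.

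Other splits of the arrays tested whether the counts need the real groups. For each comparison the 8 arrays have 35 splits into 4 and 4. For probe sets, only 1 split, the real one, gave a count as large in each comparison. The counts were 2515 against at most 130 for NEUROG2 with control and 25 against at most 7 for NEUROG2AQ with control. For NEUROG2 with NEUROG2AQ they were 2286 against 0. Highest of 35 splits is the most this test can show, without adjustment over the comparisons, so it does not exclude chance. A split that mixes the groups also puts any difference between them into the spread within groups, which lowers its count. For lists, 10 of 35 splits gave as many as the real 9 for NEUROG2 with control, with at most 10 in another, so chance cannot be excluded for that count. Each of the other 9 differs from the real split by 1 exchanged array per group. Splits that divide both groups evenly still took 0 to 6 lists past the threshold in this comparison, with 0 probe sets called. With the preset correlation, lists thus also passed where the groups were balanced. For NEUROG2AQ with control (13 lists against at most 11) and NEUROG2 with NEUROG2AQ (10 against at most 9) only 1 split, the real one, gave as many. Evenly dividing splits took 0 to 5 lists past the threshold in each of these comparisons as well. Their list counts therefore do not exclude chance either.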
